A study of Mus musculus with 9 samples.

How the data were processed

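Poly(A) RNA from the livers of wild-type mice was sequenced 2 h after intraperitoneal injection of NaCl or of retrorsine at 25 or 50 mg/kg, in 3 groups of 3 libraries. The labels' protocols describe oligo(dT) enrichment, fragmentation, random-primed cDNA and PCR, and no molecular identifiers. The submitters' processing notes name HISAT2 as aligner and the mouse build GRCm38; the HISAT2 version, the counting tool, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may have been split or dropped.

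The deposited table holds 21936 genes, each with a read count per library made by the authors, whole numbers that were not normalized. It also holds FPKM values, which per the file headers are the authors' own and which equal within 1% the deposited count divided by the gene length and the library's column total, for each gene with a count; they carry no further information and were not tested. Of the gene IDs, 21894 were found in GENCODE M21, and 21694 of these had the start and end given there, which are GRCm38 coordinates as printed here. Of those found, 21857 are protein coding. Ighm and Trac of the lymphocyte list were not analysed here.

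Total counts per library were 16051919, 18501966 and 18691736 with NaCl, 17516579, 15241261 and 17330138 with 25 mg/kg, and 16530687, 15571060 and 16180462 with 50 mg/kg. For a group with no reads, a fold bound was computed against 3 counts over the group; such bounds cover counting error only. Libraries of a group differed far beyond sampling noise (mean chi-square per gene between 43.9 and 112.6), so none was the same library counted again. Separate preparations of the same RNA sample are not excluded by this. The acute phase levels given in the results argue against them with NaCl and 50 mg/kg.

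The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, leaving 12557, scaled with TMM, and fitted with 1 mean per group over all 9 libraries (6 residual degrees of freedom, no block). The quasi-likelihood F test gave p-values, adjusted by Benjamini-Hochberg within a comparison with a threshold of 0.05, and the SE is the absolute log2 fold change over the square root of F. Levels are CPM on TMM-scaled library sizes; log2 CPM used a prior count of 2.

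There were 30 gene lists fixed before the data were examined, as were the main tests, most of the alternatives and the rule for named genes. The lists cover stress, metabolic and clock programs, the cell types of liver, and blood, pancreas, adipose and mitochondrial transcripts; their names and results stand in the report. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, beside an estimated correlation and fry, with adjusted p-values over the lists of a comparison. Some genes stand in several lists.

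Genes were named by this rule: among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted name, the 8 largest rises and 8 largest falls; up to 3 members with the lowest adjusted p per list, or up to 2 members with the lowest p where none passed; and in every comparison Atf3, Gpx4, Slc7a11, Acsl4, Hmox1, Ptgs2, Chac1 and Cyp3a11. The list members printed are examples among those the rule allows, and some genes the rule takes are not reported here. Cd3g, Lcn2, S100a9, Cxcl1 and Saa1, where given per library, were chosen after their values were seen, as were the 5 rises and 5 falls with the lowest adjusted p.

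Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), DESeq2 1.42.0, limma-voom, other filters, a fold limit, fits of only the groups compared, a replicate block and leaving out each library in turn. After the data were seen, fits without NaCl replicate 1 and 50 mg/kg replicate 2 (rich in acinar reads), without NaCl replicate 1 and 50 mg/kg replicate 3 (rich in cytokine transcripts), and without genes that follow the acinar list were added. The last was first run with a looser choice of genes (correlation over 0.9 with the list's profile, 77 genes) and then with the correlation over 0.95 that had been intended (39 genes); both are given in the closing section.

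The procedure was tested on simulated data of 12220 genes with known changes. For 25 mg/kg against NaCl, 17.7% of 2-fold and 82.5% of 4-fold changes were recovered and 3.96% of calls were false; for 50 mg/kg against NaCl these were 15.6%, 78.4% and 5.21%. With no simulated difference between the doses 0 genes were called. For 50 mg/kg against NaCl, camera called the changed list (adjusted p = 1.4e-27) and 0 of 29 random lists. Genes were simulated independently of each other, whereas the estimated correlation reached 0.943 in the real acinar list at 25 mg/kg. This check therefore does not cover lists of correlated genes. A simulated slope of -0.2 on gene span was fitted as -0.199. Changes of 2-fold were thus mostly missed in this simulation. It changed 96 genes 2-fold and 97 genes 4-fold, far fewer than were called in the data. Recovery after adjustment depends on that number, so these rates do not carry over to the real comparisons. Figures were drawn with matplotlib 3.10.9.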

Results

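The transcriptome of wild-type mouse liver was measured 2 h after an intraperitoneal injection of NaCl, of retrorsine at 25 mg/kg or of retrorsine at 50 mg/kg, with 3 libraries per group. Retrorsine is a pyrrolizidine alkaloid, a class of plant toxins that liver cytochrome P450 enzymes turn into reactive pyrroles. The series title places the study in the field of liver injury, the transcription factor ATF3 and ferroptosis, an iron-dependent form of cell death. Total counts per library ranged from 15241261 to 18691736. The labels speak of repetitions and do not say that the libraries of a group came from separate animals. The p-values therefore measure only the spread between these samples. The mean log2 CPM of the acute phase list, centred per gene, was 1.73, -0.15 and 0.81 with NaCl. After 50 mg/kg it was 0.59, -1.49 and 1.88. Such spreads argue against repeat preparations of the same RNA sample in these groups, but separate animals remain unstated. Unless another test is named, every adjusted p for a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12557 genes, and means are CPM (counts scaled by library size) ± SD with n = 3.

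The first comparison asked which transcripts differed after 25 mg/kg of retrorsine. Atf3 (ENSMUSG00000026628, GRCm38 chromosome 1, 191170296 to 191218039), a stress-induced transcription factor, rose from 20.8 ± 19 CPM to 173 ± 26 CPM, a log2 fold change of 3.06 (SE 0.63, adjusted p = 0.013). Trib3, a pseudokinase of the integrated stress response, rose from 4.18 ± 0.59 to 40.6 ± 6.2 CPM, and Srxn1, which repairs oxidised peroxiredoxins, rose from 47.8 ± 3.2 to 816 ± 65 CPM. Acaca and Acacb encode the acetyl-CoA carboxylases of fatty acid metabolism. They fell from 228 ± 30 to 50.3 ± 8.1 CPM and from 434 ± 55 to 125 ± 8.3 CPM. In all, 1690 genes changed, 741 higher and 949 lower. The groups did not overlap for 36.5% of genes, where chance gives 10%.

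By size, Sprr1a (log2 fold change 8.29), Hist1h4m, Fst (6.06), Sema4f (5.81), Gsta1 (5.62), H1f4 (5.33), Ugt2b37 (5.31) and H4c14 (4.66) rose most. Fst encodes follistatin, a secreted activin antagonist, and went from 0.431 to 29.5 CPM. Hist1h4m had no reads in the NaCl libraries and was at least 30.5-fold higher. Gsta1, Ugt2b37 and the histone genes have near-identical copies, so their counts are uncertain, and the H4c14 and Hist1h4m calls were lost in 8 and 7 of 21 alternatives. The genes that fell most were Clps, Reg1, Reg2, Prss2, Try5, Pnliprp2, Ctrb1 and Cel, all genes of the exocrine pancreas. Clps, Reg1, Reg2 and Pnliprp2 had no reads after 25 mg/kg and were at least 946-fold, 883-fold, 708-fold and 350-fold lower. These sizes are not firm, because they rest mostly on NaCl replicate 1: Clps stood at 168, 19.1 and 7.13 CPM in the NaCl libraries, and its log2 fold change ranged from -13.60 to -9.84 over the alternatives. Among the fixed acinar markers, 11 of 11 tested fell, also when adjusted over the list alone (camera adjusted p = 4.2e-06, adjusted p = 0.70 with an estimated correlation). Acinar reads made up 0.616%, 0.107% and 0.0276% of the NaCl libraries, against 0.00184%, 0.00114% and 0.00157% after 25 mg/kg. Without any 1 of the 25 mg/kg libraries edgeR called 0 of these acinar genes, and without NaCl replicate 1 it called 4; the calls of the 8 largest falls were each lost in 3 to 6 of 20 alternatives, limma-voom among them.

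Among NRF2 targets and glutathione genes, 8 of 21 rose and 0 fell (10 up and 1 down when adjusted over the list alone). Besides Srxn1 and Gsta1, Ugdh, which makes UDP-glucuronate, rose by 1.52 on the log2 scale (SE 0.22, adjusted p = 0.0038). The list stood higher than other genes (camera adjusted p = 4.2e-06, adjusted p = 0.23 with an estimated correlation). Of 30 ferroptosis genes, 6 rose and 0 fell (9 and 2 over the list alone), among them Nfe2l2, which encodes NRF2, at 1.29 (SE 0.22) and Gclc, the catalytic subunit of glutathione synthesis, at 1.23 (SE 0.22). The members that rose include glutathione genes of the NRF2 list, and Atf3 is shared with the stress lists. The camera adjusted p was 0.045 for ferroptosis, and the adjusted p = 0.60 with an estimated correlation. The list tests did not account for the trend with gene span given further below. Gpx4, the lipid peroxidase that opposes ferroptosis, had a log2 fold change of 0.28 (adjusted p = 0.37), Acsl4 of -0.10 (0.84) and Hmox1 of -0.76 (0.62). The direction of these last 2 turned without a single library: Hmox1 was at 0.68 without NaCl replicate 1, and Acsl4 at 0.03, 0.04 and 0.08 without NaCl replicate 1, NaCl replicate 3 and 25 mg/kg replicate 1. Slc7a11 and Ptgs2 were too low to test, at 0.019 and 0.0192 CPM after 25 mg/kg. Chac1, a glutathione-degrading enzyme, had a log2 fold change of -2.28 (adjusted p = 0.061).

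In the integrated stress response list 5 of 19 members rose and 0 fell (6 up and 2 down over the list alone), led by Trib3, Atf3 and Ppp1r15a (1.56, SE 0.35), and the list itself did not pass (camera adjusted p = 0.083). Of 23 p53 targets, 4 rose and 0 fell (6 and 0 over the list alone), including the polo-like kinases Plk2 (1.53, SE 0.24) and Plk3 and the stress sensor Sesn2 (camera adjusted p = 0.00054, adjusted p = 0.23 with an estimated correlation). Immediate early genes gave 5 rises among 24 (5 up and 2 down over the list alone), with Dusp1, a MAP kinase phosphatase, at 1.46 and Myc at 1.59 (camera adjusted p = 0.33). Heat shock had 1 rise, Hspa8, among 13 genes (0 over the list alone); its call was lost in 7 of 21 alternatives, and edgeR called 0 heat shock genes without NaCl replicate 2, NaCl replicate 3, 25 mg/kg replicate 1, 25 mg/kg replicate 3 or 50 mg/kg replicate 1. Without NaCl replicate 3 the Atf3 call ended (adjusted p = 0.058, the highest over 21 alternatives, the lowest log2 fold change being 2.64), and 2 stress response, 2 ferroptosis, 1 immediate early and 2 p53 members were called. Without 25 mg/kg replicate 3 these counts were 2, 3, 2 and 1, and without 25 mg/kg replicate 1 they were 3, 3, 3 and 2. Without NaCl replicate 1 or NaCl replicate 2, 3 stress response members were called, and without NaCl replicate 2 or 25 mg/kg replicate 2, 2 p53 targets. The calls of Ppp1r15a, Plk3, Sesn2 and Myc were lost in 3, 5, 5 and 6 of 21 alternatives.

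In fatty acid synthesis, 4 of 16 genes fell and 1 rose (6 and 2 over the list alone): besides the carboxylases, Elovl6 fell by 1.63 on the log2 scale (SE 0.23). The list stood lower (camera adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation). G6pc, the last step of glucose release, rose by 3.42 (SE 0.60, adjusted p = 0.0073), 1 of 2 rises beside 1 fall among 12 gluconeogenesis and fasting genes (2 and 1 over the list alone); Pdk4 was the other. PPARalpha targets gave 3 rises and 2 falls among 20 (4 and 2 over the list alone), with Angptl4 at 1.34. Glucocorticoid receptor targets gave 3 rises and 2 falls among 11 (3 and 4 over the list alone), the falls being Fkbp5 (-2.05) and Zbtb16 (-2.75). In the clock list 2 of 18 rose and 3 fell (3 and 5 over the list alone), among them Cry2 at 1.32 (SE 0.18) and Usp2 at -2.24 (SE 0.36). Cholesterol synthesis gave 3 rises and 1 fall among 24 (3 and 2 over the list alone), with Dhcr7 at 1.19. The Pdk4 and Dhcr7 calls were lost in 2 and 5 of 21 alternatives. The camera test called none of these last 5 lists. In the immediate early, gluconeogenesis, glucocorticoid receptor and hepatocyte lists the median, the mean and the camera test differed in sign. Without 25 mg/kg replicate 3, 3 fatty acid synthesis, 1 gluconeogenesis, 2 PPARalpha, 2 clock and 1 cholesterol synthesis members were called. Without NaCl replicate 3 the PPARalpha, clock and cholesterol counts were 3, 2 and 1, and without 25 mg/kg replicate 1 they were 3, 3 and 1. Without NaCl replicate 1, 1 gluconeogenesis, 3 PPARalpha and 3 clock members were called, and without NaCl replicate 2, 3 clock and 0 cholesterol synthesis members.

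ER chaperones gave 4 falls among 17 (4 over the list alone), among them Sel1l, a part of ER-associated degradation, at -1.01 (SE 0.17), Hyou1 at -0.69 and Dnajc3 at -0.57. This count fell to 2 without NaCl replicate 2 or 25 mg/kg replicate 3, and to 1 without NaCl replicate 1, NaCl replicate 3, 25 mg/kg replicate 1, 25 mg/kg replicate 2 or 50 mg/kg replicate 2. Of 20 acute phase genes, 2 fell, Itih4 at -1.09 and Fgg at -1.08 (7 over the list alone; camera adjusted p = 5.7e-05, adjusted p = 0.79 with an estimated correlation), and edgeR called 0 of these without NaCl replicate 1, NaCl replicate 3 or any of the 25 mg/kg libraries, 1 without NaCl replicate 2 or 50 mg/kg replicate 1, 5 without 50 mg/kg replicate 3 and 11 without 50 mg/kg replicate 2. Onecut1, a hepatocyte transcription factor, fell by 2.85, and Nr1i2 rose by 0.80, among 25 hepatocyte markers (0 up and 1 down over the list alone); 1 was called without any 1 of the NaCl or 25 mg/kg libraries and 4 without 50 mg/kg replicate 3. Bile acid genes gave 1 rise among 17, Abcb4 (1 over the list alone). Of the genes named in this paragraph, Sel1l and Onecut1 kept their calls under all 21 alternatives, and those of Itih4, Fgg, Nr1i2, Abcb4, Cd68, Pkhd1, Hyou1 and Dnajc3 were lost in 6, 10, 10, 6, 5, 12, 12 and 11. Kupffer cell and macrophage markers gave 1 rise among 14, Cd68 (1 over the list alone; camera adjusted p = 0.021, adjusted p = 0.79 with an estimated correlation), and cholangiocyte markers 1 fall among 7, Pkhd1 (2 over the list alone). In 11 lists edgeR called none of 124 members, also when adjusted over the list alone, with 12 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom. Leaving out some single libraries gave 1 member each of the P450, lymphocyte, stellate cell and sinusoidal endothelial lists. The 11 were NF-kB and cytokines, xenobiotic P450 enzymes, hypoxia, cell cycle, sinusoidal endothelium, neutrophils and monocytes, lymphocytes, stellate cells and fibroblasts, erythroid and blood, adipose and mesothelium, and mitochondrial transcripts. The fry test asks whether the genes of a list move on balance one way and does not compare them with other genes. By fry the P450 list moved up (adjusted p = 0.013, camera adjusted p = 0.17), as did NRF2 targets (fry adjusted p = 0.0052), p53 targets (0.012) and ferroptosis (0.048), while fatty acid synthesis moved down (0.011). The other 25 lists did not pass fry. Cyp3a11, of the P450 family that activates pyrrolizidine alkaloids, stood at 3599 ± 200 CPM against 3029 ± 275 CPM (adjusted p = 0.39).

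Chosen after their values were seen, the 5 lowest adjusted p among rises were Otud1 (3.72), Srxn1, Tnfrsf12a (3.81), Ccdc120 (3.08) and Slc20a1 (3.11), and among falls Acaca, Acacb, Itpr1 (-1.75), Mical2 (-1.89) and Arid1b (-2.49). The count of changed genes was 626 without 25 mg/kg replicate 3, 751 without NaCl replicate 3, 753 without 25 mg/kg replicate 1, 896 without NaCl replicate 1 and 1068 without NaCl replicate 2. With a log2 fold change of at least 1 required, 1073 genes remained.

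**Figure D1:**
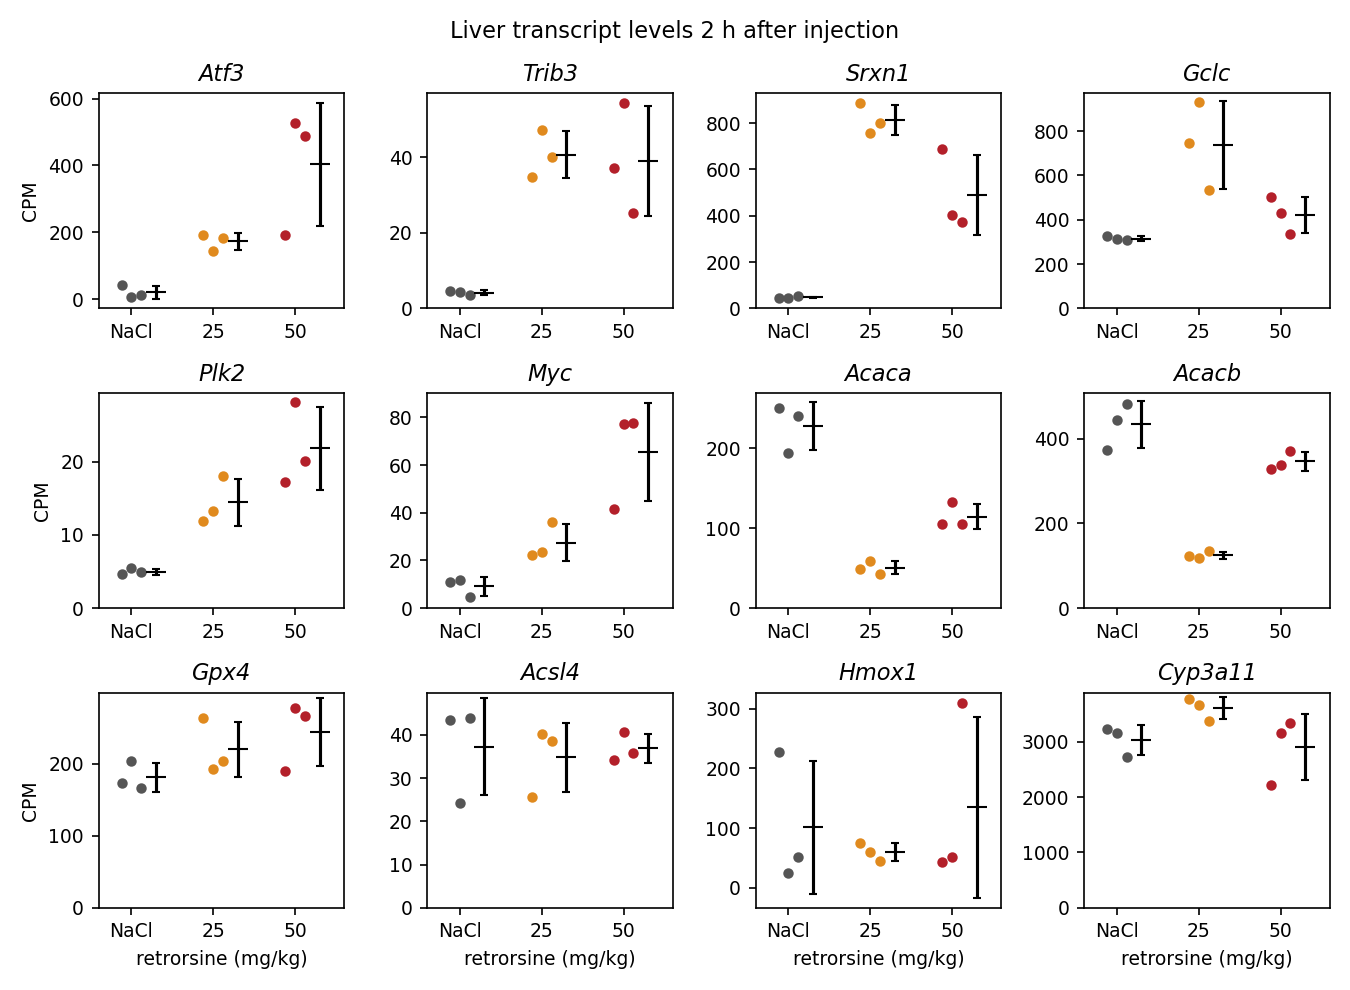
CPM of 12 genes (y axes, linear) in the 9 libraries by retrorsine dose in mg/kg (x axes); points are libraries, and the bar beside them is the mean ± SD of 3. Atf3 stood at 7.02 to 42.8 CPM with NaCl and at 143 to 527 CPM with retrorsine, while Hmox1 had 1 high NaCl and 1 high 50 mg/kg library.

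The second comparison asked the same at 50 mg/kg. Atf3 rose to 403 ± 180 CPM, a log2 fold change of 4.28 (SE 0.66, adjusted p = 0.0045), and its call held under every alternative run. Trib3 rose to 38.9 ± 15 CPM and Srxn1 to 488 ± 170 CPM. Gdf15, a stress-induced cytokine and p53 target, rose from 5.64 ± 2.8 to 41.8 ± 18 CPM (log2 fold change 2.89, SE 0.53), and Myc from 9.12 ± 4.1 to 65.5 ± 21 CPM (2.85, SE 0.40). Scd1, the stearoyl-CoA desaturase, rose by 1.94 (SE 0.30), and Ppara, the receptor that drives fatty acid oxidation genes, fell by 1.86 (SE 0.36). In all, 1896 genes changed, 890 higher (46.9%) and 1006 lower. Scaled by library totals alone, 656 were higher (35.5%) and 1194 lower. The groups did not overlap for 35.0% of genes, where chance gives 10%.

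By size, Hist1h4m (no reads with NaCl, at least 33.1-fold higher), Tctex1d4 (6.88), Sprr1a (6.78), Lif (6.58), Cd3e (5.80), Ugt2b37 (5.62), H1f4 (5.61) and Sema4f (5.16) rose most. Lif encodes a cytokine of the interleukin-6 family, and its call was lost in 8 of 20 alternatives. The Hist1h4m call was lost in 7 of 20, and those of Sprr1a and Sema4f in 1 of 21 each. Cd3e, a T cell receptor chain, stood at 8.38, 32.3 and 3.13 CPM after 50 mg/kg, against 0.202, 0.202 and 0.351 CPM with NaCl; Cd3g of the same complex was at 0.608, 0.26 and 0.477 CPM. The largest falls were Reg2 (-6.24), Dmbt1 (-5.97), Reg3b (-5.53), Reg3a (-5.46), Pdia2 (-5.33), Reg3g (-5.16), Zg16 (-4.82) and Klk1 (-4.59), again mostly genes made in the pancreas or gut, and their calls were lost in between 2 and 12 alternatives. Neither their sizes nor their order were firm: over the alternatives the log2 fold change of Reg2 ranged from -10.25 to -3.65, of Reg3b from -12.02 to -3.12, of Reg3a from -11.69 to -3.48 and of Zg16 from -9.28 to -2.19. The acinar markers had 11 members at an unadjusted p under 0.05, all lower, with 0 of 11 past edgeR's threshold, 1 past that of DESeq2 and 1 past that of limma-voom, and 11 when adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.88 with an estimated correlation). Acinar reads were 0.0372% of 50 mg/kg replicate 2, above NaCl replicate 3, and 0.00105% and 0.00154% of the other 50 mg/kg libraries. Without 50 mg/kg replicate 2, 10 acinar markers were called lower, and without NaCl replicate 3, 1.

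Of 23 p53 targets, 8 rose and 0 fell (10 and 0 over the list alone), among them Plk2 at 2.13 (SE 0.24) and Plk3 at 2.20 (SE 0.38); the camera adjusted p was 5.3e-06, with an adjusted p = 0.10 with an estimated correlation. In the integrated stress response 5 of 19 rose and 0 fell (6 and 0 over the list alone), with Ppp1r15a, which restarts translation, at 2.56 (SE 0.36; camera adjusted p = 0.00055, adjusted p = 0.32 with an estimated correlation). Immediate early genes gave 7 rises among 24 (8 over the list alone), including Myc, Jund at 1.97 and Dusp1 at 1.87 (camera adjusted p = 7.9e-06, adjusted p = 0.88 with an estimated correlation). As a whole this list was high in only 2 of the 3 libraries: its mean centred log2 CPM was -0.16, 0.93 and 1.58 after 50 mg/kg, against 0.43, -1.25 and -0.54 with NaCl. NRF2 targets gave 6 rises among 21 (7 over the list alone), with Gsta1 at 3.73 and G6pdx at 1.04 (camera adjusted p = 0.0012, adjusted p = 0.32 with an estimated correlation). Without NaCl replicate 2, 1 NRF2 member was called, without NaCl replicate 3, 2, and without NaCl replicate 1, 25 mg/kg replicate 1, 25 mg/kg replicate 3 or 50 mg/kg replicate 2, 3. Without NaCl replicate 3, 4 p53 targets were called, and without 50 mg/kg replicate 2, 5. The Gsta1 and G6pdx calls were lost in 4 of 20 and 8 of 21 alternatives. Ferroptosis genes gave 5 rises among 30 (6 over the list alone), with Nfe2l2 at 1.22 and the polyamine enzyme Sat1 at 1.46 (camera adjusted p = 0.019, adjusted p = 0.52 with an estimated correlation). Gpx4 had a log2 fold change of 0.43 (adjusted p = 0.15), Acsl4 of -0.01 (0.98), Hmox1 of 0.42 (0.78), Chac1 of -1.21 (0.25) and Cyp3a11 of -0.06 (0.84), and Slc7a11 and Ptgs2 were again too low to test. Without single libraries Hmox1 ranged from -1.11 to 1.85, Acsl4 from -0.25 to 0.12 and Cyp3a11 from -0.17 to 0.11, so none of these 3 kept its direction.

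Fatty acid synthesis gave 3 rises and 1 fall among 16 (4 and 1 over the list alone), the rises including Scd1 and Pnpla3 (1.40) and the fall being Acaca, from 228 to 114 ± 15.8 CPM (camera adjusted p = 0.26). In the clock list 2 rose and 5 fell of 18 (4 and 6 over the list alone), with Cry2 at 1.09, Usp2 at -1.73 and Hlf at -0.80. Glucocorticoid receptor targets gave 1 rise and 2 falls among 11 (2 and 2 over the list alone), the falls being Zbtb16 at -2.86 and Fkbp5 at -1.88. PPARalpha targets gave 2 rises and 3 falls among 20 (3 and 3 over the list alone), with Pdk4 at 1.77, which was also the 1 rise among 12 gluconeogenesis genes (1 over the list alone). Cholesterol synthesis gave 2 rises and 1 fall among 24 (2 and 1 over the list alone). Heat shock gave 2 rises among 13 (2 over the list alone), Bag3 at 1.29 and Hspa8 at 0.91. ER chaperones gave 2 falls among 17 (2 over the list alone), Sel1l at -1.38 and Dnajc3 at -0.60; 1 was called without NaCl replicate 1, NaCl replicate 3, 25 mg/kg replicate 1, 25 mg/kg replicate 3, 50 mg/kg replicate 2 or 50 mg/kg replicate 3. The Dnajc3, Hspa8, Hlf, Pnpla3, Pdk4, Bag3, Usp2, Fkbp5, Acaca and Ptprb calls were lost in 11, 8, 6, 4, 4, 2, 1, 1, 1 and 1 of 21 alternatives. Lymphocyte markers gave 2 rises among 7 (2 over the list alone), Cd3e and Cd79a, and the Cd79a call was lost in 11 of 20 alternatives. Cd68 rose by 1.16 (1 of 14 macrophage markers, 1 over the list alone), Ptprb fell by 0.92 (1 of 19 endothelial markers, 1 over the list alone, 2 called without NaCl replicate 1 and 3 without 50 mg/kg replicate 1) and Onecut1 fell by 1.79 (1 of 25 hepatocyte markers, 0 over the list alone; call lost in 10 of 21 alternatives). Without NaCl replicate 3, 2 clock, 2 PPARalpha, 2 fatty acid and 1 cholesterol synthesis members were called, and edgeR called 0 heat shock and 0 gluconeogenesis members. Without NaCl replicate 2 the PPARalpha, fatty acid and cholesterol counts were 2, 2 and 1, and those of heat shock and gluconeogenesis 0. The gluconeogenesis count was 2 without 25 mg/kg replicate 1 and 3 without 25 mg/kg replicate 2. Without NaCl replicate 1, 2 clock and 3 PPARalpha members were called, and without 50 mg/kg replicate 2, 4 clock, 3 PPARalpha and 1 cholesterol synthesis members, which was also the cholesterol count without 50 mg/kg replicate 1.

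In 13 lists edgeR called none of 153 members, with 28 at an unadjusted p under 0.05, 11 called by DESeq2 and 3 by limma-voom. Besides the acinar markers, these were acute phase, NF-kB and cytokines, xenobiotic P450 enzymes, bile acid genes, hypoxia, cell cycle, neutrophils and monocytes, stellate cells and fibroblasts, cholangiocytes, erythroid and blood, adipose and mesothelium, and mitochondrial transcripts; edgeR called 0 members of these 12 when adjusted over the list alone. For NF-kB and cytokines this rested on the libraries used: of 17 members, 2 were higher without NaCl replicate 1, 6 without NaCl replicate 1 and 50 mg/kg replicate 2, and 2 without NaCl replicate 1 and 50 mg/kg replicate 3. Without 50 mg/kg replicate 1, 2 erythroid members were called, and leaving out some single libraries gave 1 member each of the hypoxia, P450, bile acid, acute phase, stellate cell and cholangiocyte lists. By fry, p53 targets (adjusted p = 0.0055), NRF2 targets (0.012), the integrated stress response (0.014) and ferroptosis (0.033) moved up, and the other 26 lists did not pass. In the acute phase, P450, cholesterol synthesis, hypoxia and adipose lists the median, the mean and the camera test differed in sign. Cytokine and acute phase levels varied within the group: Lcn2 stood at 1248, 47.4 and 2761 CPM after 50 mg/kg and at 1348, 195 and 518 CPM with NaCl, and S100a9, a neutrophil protein, reached 103 CPM in 50 mg/kg replicate 3 against 5.29 and 3.57 CPM in the others of its group. Chosen after their values were seen, the 5 lowest adjusted p were Otud1 (3.17), Srxn1, Tnfrsf12a (3.73), Ccdc120 (3.30) and Pvr (3.46) among rises and Tns1 (-1.45), Itpr1 (-1.52), Mical2 (-1.69), Kmt2c (-1.97) and Wdr7 (-2.24) among falls. The count was 700 without NaCl replicate 3, 1092 without NaCl replicate 1, 1138 without NaCl replicate 2 and 1151 without 50 mg/kg replicate 2, and 1193 with a log2 fold change of at least 1. With NaCl replicate 1 and 50 mg/kg replicate 2, both rich in acinar reads, left out, 653 genes changed at 50 mg/kg and 975 at 25 mg/kg.

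**Figure D2:**
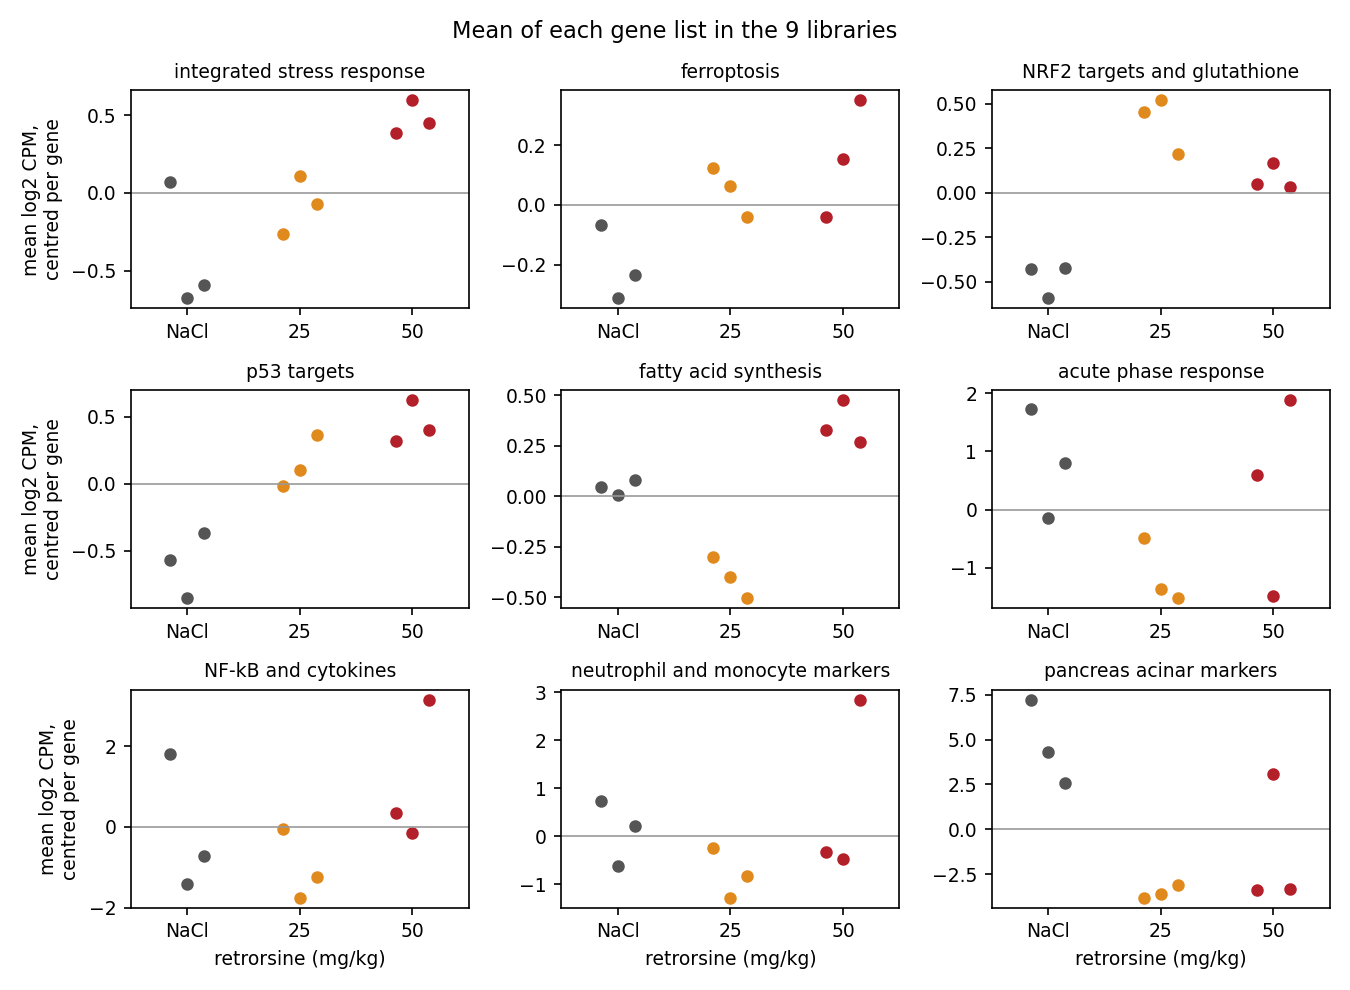
Mean over list members of log2 CPM, centred on each gene's mean over the 9 libraries (y axes), by retrorsine dose in mg/kg (x axes); points are libraries. The NRF2 list lay between -0.595 and -0.424 with NaCl and between 0.035 and 0.52 with retrorsine, and the acinar list was high in 50 mg/kg replicate 2 (3.07) as in the NaCl libraries.

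The third comparison set the doses against each other. Acacb, the mitochondrial acetyl-CoA carboxylase, was the 1 gene of 12557 past the threshold, at 347 ± 23 CPM after 50 mg/kg against 125 ± 8.3 CPM after 25 mg/kg (log2 fold change 1.47, SE 0.15, adjusted p = 0.021), and its call was lost in 11 of 21 alternatives, among them leaving out any 25 mg/kg library, while its log2 fold change stayed between 1.38 and 1.52. At an unadjusted p under 0.05 there were 1079 genes, limma-voom called 1 and DESeq2 called 71. The groups did not overlap for 11.4% of genes, where chance gives 10%. Atf3 had a log2 fold change of 1.22 (SE 0.59, adjusted p = 0.61), G6pc of -2.03 (SE 0.57, 0.55), Gclc of -0.81 and Ugdh of -0.83 (both 0.55).

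Fatty acid synthesis was the list that stood apart with an estimated correlation too (camera adjusted p = 5.3e-17, adjusted p = 0.013 with an estimated correlation), with a median log2 fold change of 0.81, 1 of 16 members past the threshold and 11 higher when adjusted over the list alone. Camera with its preset correlation called 12 lists, and 1 with the estimated correlation. Higher at 50 mg/kg were immediate early genes (4.2e-12), NF-kB and cytokines (2.0e-10), acute phase (8.7e-10), acinar markers (0.00010), neutrophils and monocytes (0.00045), integrated stress response (0.00052), p53 targets (0.018) and hypoxia (0.030). Lower were sinusoidal endothelium (6.5e-05), Kupffer cells (0.00058) and NRF2 targets (0.0099). With an estimated correlation the adjusted p = 0.35 for 9 of these, 0.36 for neutrophils and monocytes and 0.45 for acinar markers, and edgeR called none of their members; fry called fatty acid synthesis (adjusted p = 0.0025) and 0 of the others. Single libraries stood far from the rest of the 50 mg/kg group in some of these lists. By mean centred log2 CPM, the acinar list was at 3.07 in 50 mg/kg replicate 2 against -3.37 and -3.29 in the other 2, which lay within the 25 mg/kg range of -3.81 to -3.11. In 50 mg/kg replicate 3 the neutrophil list was at 2.84 against -0.32 and -0.47, the NF-kB list at 3.15 against 0.34 and -0.14, and the hypoxia list at 0.97 against -0.13 and 0.03. The acute phase list spanned -1.49 to 1.88 in the 3 libraries. The Kupffer list was low in 50 mg/kg replicate 2 (-0.68 against 0.20 and 0.14), and in 50 mg/kg replicate 1 the endothelial list (0.17) lay within the 25 mg/kg range of 0.15 to 0.20 and the immediate early list (-0.16) within that of -0.73 to -0.10. Over the 29 lists other than fatty acid synthesis, edgeR called 0 of 450 members, with 115 at an unadjusted p under 0.05, 6 called by DESeq2 and 0 by limma-voom. Over the list alone, 1 NRF2 member was higher and 5 lower, 6 neutrophil members were higher, 9 acinar members were higher and 1 Kupffer member was lower. In the other 18 lists the camera adjusted p was above the threshold, and over the list alone 1 lymphocyte member was higher and 1 lower; the heat shock, P450, cholesterol synthesis, cell cycle, lymphocyte and stellate cell lists had a median, mean and camera test that differed in sign.

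The log2 fold changes of the 2 doses against NaCl correlated across genes (Pearson r = 0.770), and 80.1% of genes had the same sign; genes are not independent replicates. Because both doses share the NaCl libraries, unchanged groups simulated in 50 draws gave a median r of 0.495 and 66.6% of the same sign. The covariance was 0.688 against a simulated 0.0972, a difference of 0.591. These draws simulated genes independently of each other, whereas genes of some real lists were correlated. They therefore do not show how far such values can vary between unchanged groups. Both doses raised 536 genes and lowered 669, and 0 genes were called in opposite directions. Independent lists would share 52.5 and 76.0, a value that leaves out the shared NaCl libraries. The simulation gave 0, but it holds no effects, so neither value is a fair measure for these overlaps. Part of the overlap may come from the shared controls, as 3 NaCl libraries are too few to give each dose its own.

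Across genes, the fold change followed the length of the gene on the chromosome. In the shortest decile of genomic span (median 3.14 kb) the median log2 fold change was 0.28 at 25 mg/kg and 0.36 at 50 mg/kg. In the longest decile (median 184 kb) it was -0.79 and -0.84, with 447 genes lower and 15 higher at 25 mg/kg, and 483 lower and 14 higher at 50 mg/kg. All genes together gave 949 falls at 25 mg/kg and 1006 at 50 mg/kg. The next longest decile (median 87.9 kb) held 202 and 256 of these falls. Whether span accounts for the single falls named above was not tested. Spearman's rho of span with log2 fold change was -0.437 and -0.515. Acaca spans 272 kb and Srxn1 5.86 kb. The relation was noticed after the values were seen. The list tests against NaCl did not remove this trend, and whether span played a part in them was not tested. Camera at its preset correlation called the ferroptosis, NRF2 and p53 lists higher at both doses. The median log2 fold change of the ferroptosis list (0.27 and 0.37) was close to that of the shortest decile. The medians of the NRF2 list (0.59 and 0.42) and the p53 list (0.62 and 0.85) lay above it.

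**Figure D3:**
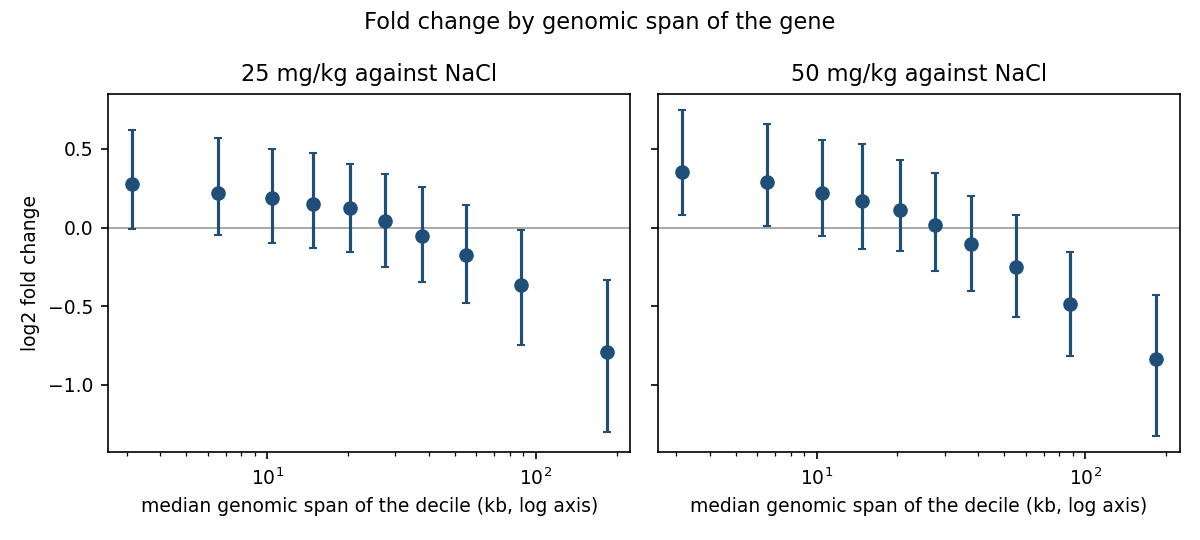
Median log2 fold change with the middle 50% of genes as bars (y axis) in 10 deciles of genomic span, placed at their median span in kb (x axis, log scale), for each dose against NaCl. The medians fall from 0.28 and 0.36 in the shortest decile to -0.79 and -0.84 in the longest.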

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

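The tests of mRNA length and of the span slope per library, of the acinar ratios and shares, and of feeding state and gene span for fatty acid synthesis were chosen after the result was seen, while the comparisons of groups, the list tests and the splits of the samples were planned, and the test without acinar-rich libraries for gene span was written before its value was computed.

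Acacb stood out because its change differed between the doses. Its log2 fold change of 50 against 25 mg/kg was 1.47 in the direct test of the difference (adjusted p = 0.021), at 123, 119 and 135 CPM after 25 mg/kg and 329, 339 and 372 CPM after 50 mg/kg. It is part of a wider pattern, since the fatty acid synthesis list had a median log2 fold change of 0.81. The linear trend with gene span between the doses was too weak to account for it (slope -0.049 per doubling of span). With that trend removed the median was 0.72. Whether span played a part in the list's changes against NaCl was not tested. Feeding state cannot be told apart, because gluconeogenesis and fasting genes went both ways (median 0.31, camera adjusted p = 0.65 with an estimated correlation), and no label gives feeding. By the rule as written for this test, a positive median would have counted against feeding state. The rule as run also required an adjusted p under 0.05 with an estimated correlation, which was not met. A dose effect on the pathway stays open as a hypothesis. The Acacb call was lost in 11 of 21 alternatives, but its log2 fold change stayed between 1.38 and 1.52, and the list passed camera with an estimated correlation (adjusted p = 0.013) and fry (0.0025), with 11 of 16 members higher when adjusted over the list alone.

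The lower level of genes with a long genomic span was not a matter of mRNA length: within deciles of mRNA length the median Spearman correlation was -0.322 at 25 mg/kg and -0.389 at 50 mg/kg. It did not rest on NaCl replicate 1, 50 mg/kg replicate 2 and the genes that follow the acinar list. Without these the slope per doubling of span was -0.177 and -0.203, against -0.165 and -0.214 before. NaCl replicates 2 and 3 stayed in, with 0.107% and 0.0276% acinar reads. The test therefore does not exclude a part for acinar RNA. The slope of log2 CPM on span was lower in each of 6 treated libraries (highest -0.0637) than in each of 3 NaCl libraries (lowest 0.0128). An exact two-sided permutation test over 84 splits gave p = 0.0119, the smallest it can give. This test restates, library by library, a relation already seen in the same data, so its p is not independent support. No mechanism was tested, neither slower transcription nor shorter mRNA half-lives, and groups handled differently in ways no label gives stay open.

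Acinar transcripts were high in the NaCl libraries and in 50 mg/kg replicate 2. In these 4 libraries the 12 genes kept nearly one ratio to each other (lowest pairwise correlation 0.978), as pancreas tissue collected with the liver would give, and this may be the source; the top genes Ctrb1 and Prss2 averaged 761 and 254 CPM with NaCl. An effect of retrorsine on these transcripts cannot be told apart, since 1 treated library had a share as high as the lowest NaCl library. Carry-over between libraries would keep the same ratio and was not tested.

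For 25 mg/kg against NaCl, 1 of the 10 splits of the 6 libraries gave as many changed genes (1690, highest of the other splits 1). For 50 mg/kg against NaCl it was also 1 of 10 (1896, highest other 1), and for 50 against 25 mg/kg 2 of 10 (1, highest other 1). With 10 splits the share cannot go under 0.05.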

How the results depend on the processing

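All fits without a pair of libraries, and those without acinar-following genes, were chosen after the data were seen; the others were planned. Of 126 named gene results past the threshold, 63 stayed past it under every alternative counted for them and 0 reversed. The fold limit was not applied to these results, and a fit that gave a gene no adjusted p was not counted for it. Where no construction is named, the cause was not tested.

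For 25 mg/kg against NaCl, 50 mg/kg against NaCl and 50 against 25 mg/kg in that order, the counts were 1073, 1193 and 1 with a log2 fold change of at least 1 (fewer genes by construction), and 1108, 1229 and 0 with a replicate block. They were 975, 653 and 0 without the acinar-rich NaCl replicate 1 and 50 mg/kg replicate 2. Without the cytokine-rich NaCl replicate 1 and 50 mg/kg replicate 3 they were 1200, 1146 and 4. Both fits had fewer samples, and equally many, so sample number does not account for the gap between 653 and 1146. Between the doses, library totals alone gave 0, a fit of only those groups 0 and DESeq2 71. Without each library in turn the counts ranged from 626 to 1850, from 700 to 1921 and from 0 to 3. Without the 39 acinar-following genes they were 1633, 1887 and 1, and with the looser choice of 77 genes, run first, 1582, 1860 and 1. No pairing by replicate number was seen: 9 pairs correlated between -0.23 and 0.136, 2 over 0.1, and the own number was best in 2. So few pairs cannot exclude one.

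The correlation of the doses was 0.825 with limma-voom, 0.683 with no filter on low counts and 0.675 to 0.815 without single libraries. Of the single libraries, only 50 mg/kg replicate 1 (0.675) and 25 mg/kg replicate 3 (0.699) moved it by over 1 SD of the leave-one-out values (0.0484) from 0.770, a rule set after a more lenient jackknife error (0.129) had been tried.

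Genes that passed no threshold turned direction as follows (log2 fold change). Acsl4 at 50 mg/kg was 0.039 with limma-voom, and Upk3b at 25 mg/kg was 0.01 with the block. Without the acinar-rich pair, Acsl4 was 0.028 at 25 and 0.038 at 50 mg/kg and Hmox1 0.68 at 25 mg/kg. Without the cytokine-rich pair, Acsl4 was 0.027 and 0.136, Hmox1 0.68 at 25 mg/kg and -0.35 between the doses. Without single libraries, at 25 mg/kg Acsl4 ranged from -0.332 to 0.079, Col1a1 from -2.60 to 0.38, Hmox1 from -1.23 to 0.68, Msln from -0.91 to 0.35 and Upk3b from -0.52 to 0.56. At 50 mg/kg Acsl4 ranged from -0.25 to 0.12, Cyp3a11 from -0.17 to 0.11, Hmox1 from -1.11 to 1.85, Msln from -0.57 to 0.69 and Ngp from -2.06 to 3.69. Between the doses Acsl4 ranged from -0.094 to 0.20 and Hmox1 from -0.35 to 1.62.

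Lists turned direction as follows (camera adjusted p at the preset correlation unless fry is named). No estimated correlation was run for the fits without a pair. With all 9 libraries it was 0.778 for the acute phase list at 50 mg/kg. Without the acinar-rich pair, at 25 mg/kg NF-kB (0.665), bile acid (0.883), clock (0.993) and cell cycle (0.902); at 50 mg/kg acute phase, then called higher (0.0133), cell cycle (0.778) and mitochondrial (0.901); between the doses cholesterol (0.129) and cell cycle (0.828). Without the cytokine-rich pair, at 25 mg/kg NF-kB (0.607), bile acid (0.868), clock (0.912) and cell cycle (0.868); at 50 mg/kg clock (0.903), cell cycle (0.703) and hepatocyte (0.879); between the doses heat shock (0.307) and cell cycle (0.552). Between the doses cell cycle also turned with fry (0.995), the block (0.897) and DESeq2 size factors (0.987).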

Other observations

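Some histone genes stood among the largest rises, and no list of histone genes was tested. H1f4 went from 0.0393 CPM with NaCl to 1.77 CPM after 25 mg/kg and 2.16 CPM after 50 mg/kg, and H4c14 from 0.555 to 13.8 and 10.3 CPM, its call at 25 mg/kg being lost in 8 of 21 alternatives. Replication-dependent histone mRNAs mostly lack a poly(A) tail, and these libraries were poly(A)-selected.

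Transcripts of inflammation varied widely between libraries of a group. Cxcl1 stood at 557, 135 and 395 CPM with NaCl, at 64.2, 4.79 and 1.30 CPM after 25 mg/kg and at 16.4, 18.6 and 513 CPM after 50 mg/kg. Saa1, an acute phase protein, stood at 1439, 468 and 1205 CPM with NaCl, at 132, 15.5 and 14.7 CPM after 25 mg/kg and at 673, 10.9 and 1534 CPM after 50 mg/kg. The first principal component of log2 CPM (40.6% of the variance) separated the NaCl libraries from the treated ones, and the second (19.5%) set 50 mg/kg replicate 3 apart at 64.8.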
